A study of Homo sapiens with 2 samples.

How the data were processed

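Expression was measured with 2 Affymetrix Gene ST 1.1 arrays, which carry probe sets for whole transcripts. Both RNA samples came from the Whirly clone of BJhTERT, a human foreskin fibroblast line immortalised with telomerase. 1 culture was grown alone and the other was confronted with PC3 cells, a human prostate carcinoma line, that carried the red fluorescent protein mRFP. Per the labels' protocols, the cells were kept for 5 days on collagen and 150 ng of total RNA was converted to labelled cDNA. The labels do not say whether the tumor cells were removed before RNA was extracted.

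The deposited values are log2 expression values with 2 decimals. Per the submitters' processing notes they were made with Affymetrix Expression Console 1.3.1 and RMA, which corrects background, equalises the probe intensity distributions of the arrays and summarises the probes of each probe set. The log base was taken from that method, since the file states none. Which arrays were normalized together and the genome build are not given in the sources used here. Scanner files were not used here, so RMA could not be repeated.

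The table held 33297 rows, each with a probe set ID and a value for each array. The platform annotation listed 21236 of the IDs, of which 19181 had 1 gene symbol and 2055 had several. The other 12061 rows were unnamed. Symbols were updated through the Entrez identifier, which the RefSeq gene table of assembly GRCh38.p14 held for 19143 of the rows with 1 symbol. No coordinates were taken from it. For a gene with several probe sets, the probe set with the highest mean of the 2 arrays was kept, which gave 17958 genes. Genes with a mean under 5.04, the median of all genes, were left out of counts of large differences, which left 8988. Differences are the log2 value of the confronted array minus that of the array of cells grown alone.

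Each group had 1 array, so no significance test, standard error or p-value was computed. A threshold of 2-fold marks the size of a difference and not its significance. 34 gene lists and the settings were fixed before the data were examined. For each list the median difference was set against 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart when its percentile was below 2.5 or above 97.5, and 1.7 of 34 lists would do so by chance. The number of arrays limits the precision of every value.

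The fixed rule for named genes took the 15 largest differences in each direction among the genes kept, leaving out short noncoding RNAs, ribosomal RNAs, LOC and open reading frame names, Y-linked genes, XIST and olfactory receptors, and, from each list, up to 4 members, together with GDF15, DKK1 and EMILIN1. The pairing of values with IDs was checked before it was applied. The check used the levels of fixed marker lists, the levels of ribosomal protein and olfactory receptor genes, the correlation between 2 probe sets of 1 gene, and the share of level variance that lay between groups of probe sets annotated with the same accessions. The last 3 were chosen after the data had been seen. The share of variance was estimated as a one-way intraclass correlation. This sets the spread between groups against that within groups and can be negative. The pairing failed this check. The rule's largest differences are therefore given by the ID of their row, which marks the row and does not establish which probe set was measured. The 2 highest and 2 lowest that the rule picks are printed beside 1 higher row that it leaves out. Gene names are used only to show what the pairing assigns to them.

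The scripts were tested on simulated data. Among 17958 simulated genes, 98.0% of 50 genes raised by a log2 change of 1.5 and 96.0% of 50 genes lowered by as much passed the 2-fold threshold. Of unchanged genes, 0.07% did. The simulated noise had a standard deviation of 0.3. The real differences of the genes kept had 0.58, which mixes noise and true differences. These shares hold for the simulated noise alone, so 0.07% is not an error rate for the 2-fold counts on these arrays. With simulated rows in order, the intraclass correlation for groups of the same accessions was 0.963, and with rows shuffled it was -0.031. Each simulated group had been given 1 level plus noise, so 0.963 is not the value that correct IDs would give on real arrays. Alternatives covered the filter on level, the choice of probe set, centring, removal of the trend with level by lowess (fraction 0.3), a further quantile normalization, the threshold, and the way random lists were drawn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.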

Results

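Transcript levels were compared between Whirly fibroblasts grown alone and Whirly fibroblasts confronted with PC3 mRFP carcinoma cells, with 1 array for each. The title of the study places the comparison in a question about how fibroblasts inhibit the growth and movement of tumor cells. The values ran from 1.54 to 13.22 with a median of 4.90 on the array of fibroblasts alone, and from 1.53 to 13.30 with a median of 5.06 on the array of confronted fibroblasts (log2 RMA values, 33297 rows each). There were no replicates, so no difference below could be set against the spread between cultures.

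The rows that the annotation assigns to genes typical of fibroblasts were spread over the range of values, and so were those of genes typical of other cells. On the array of fibroblasts alone, the row assigned to COL1A1, the main chain of type I collagen, had a value of 2.64, and those of COL1A2 and SPARC, a collagen-binding matrix protein, had 3.98 and 2.57. The row of the fibronectin gene FN1 had 3.73, that of the cytoplasmic actin gene ACTB 4.99 and that of B2M, the light chain of class I HLA molecules, 3.18. FN1 and ACTB each had 2 rows, as had EPCAM, KRT18 and PECAM1 below. For these genes only the row with the higher mean is given. Other matrix rows were high, with 10.30 for the thrombospondin gene THBS1, 9.81 for COL12A1, 9.56 for the proteoglycan gene VCAN, 8.93 for COL5A1 and 8.11 for COL3A1. The row of the intermediate filament gene VIM had 8.58. Among genes typical of epithelial cells, CD24 had 12.89, MAL2 12.59 and the epithelial cadherin CDH1 11.08, while EPCAM had 4.36, KRT18 3.46, KRT7 2.39 and OVOL1 2.12. Of the 29 epithelial and PC3 carcinoma markers 6 were in the highest 10% of genes by level, as were 3 of 17 collagens and 0 of 18 fibroblast identity genes. Rows assigned to PECAM1, an endothelial adhesion molecule, and to CD3E, part of the T cell receptor complex, had 10.06 and 8.39.

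The medians of whole gene sets lay near that of all genes. The median level over both arrays was 5.18 for 13 reference housekeeping genes and 4.68 for 17 collagen genes, against 5.04 for all 17958 genes. It was 5.88 for 18 fibroblast identity genes and 5.91 for 29 epithelial and PC3 carcinoma markers. The percentile of these medians among 10000 random sets was 55.0 for the housekeeping genes, 33.5 for the collagens, 80.1 for the fibroblast genes and 84.3 for the epithelial markers. Endothelial markers had a median of 3.74 (percentile 7.42, 10 genes) and leukocyte markers 4.56 (percentile 32.3, 10 genes). The 65 ribosomal protein genes, which all growing cells transcribe strongly, had a median of 5.06, and the 335 olfactory receptor genes, which most cells outside the olfactory epithelium do not transcribe, had 5.10. All of these percentiles lay within the limits beyond which a list was said to stand apart.

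**Figure D1:**
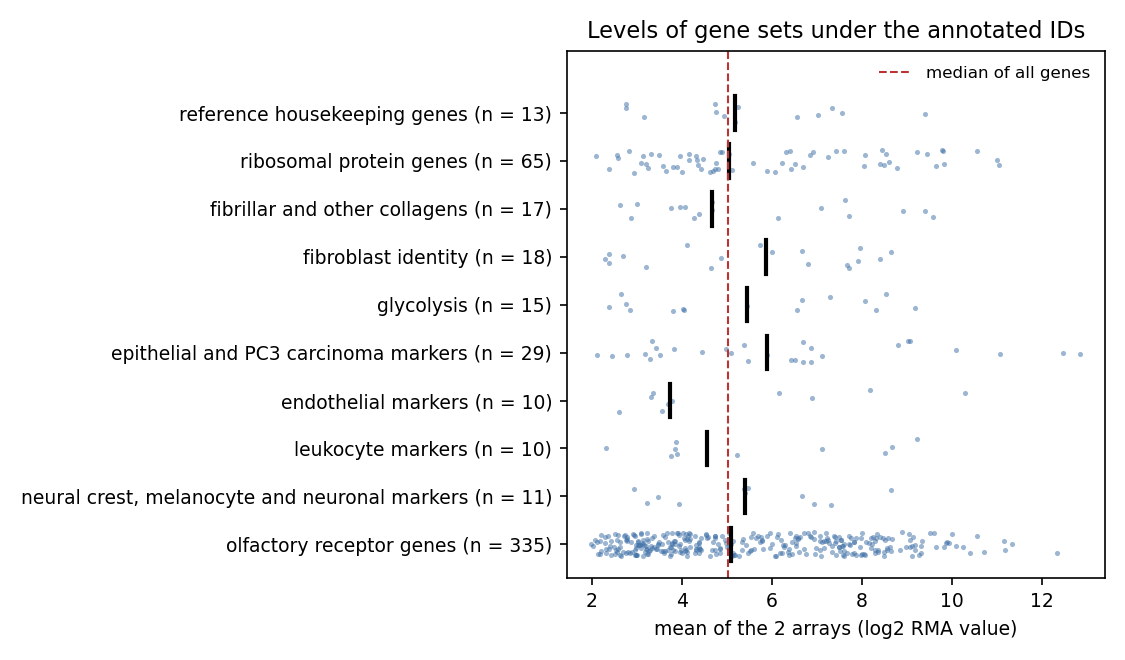
Mean of the 2 arrays (log2 RMA value) for each gene of 10 sets, as the annotation assigns rows to genes. Points are genes, black bars are set medians and the dashed line is the median of all genes, 5.04; ribosomal protein genes (median 5.06) and olfactory receptor genes (median 5.10) lie at the same level.

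Rows assigned to 1 gene did not resemble each other. Over 689 genes with exactly 2 probe sets, the mean level of one had a Pearson correlation of 0.04 with that of the other (Spearman's rho 0.04), and 95% of shuffled pairings fell between -0.08 and 0.08. The correlation of the differences between the arrays was -0.01. Among 1444 probe sets that share their accessions with another, in 596 groups, the intraclass correlation of level was 0.0021. This was inside the range of -0.06 to 0.05 that held 95% of 1000 shuffles. These are correlations across genes, which are not independent replicates. The same row did agree between the arrays, with a Pearson correlation of 0.975 and a Spearman's rho of 0.972 over all rows. The values thus agreed between the arrays row by row, but the pairing of the values with gene names was not borne out.

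**Figure D2:**
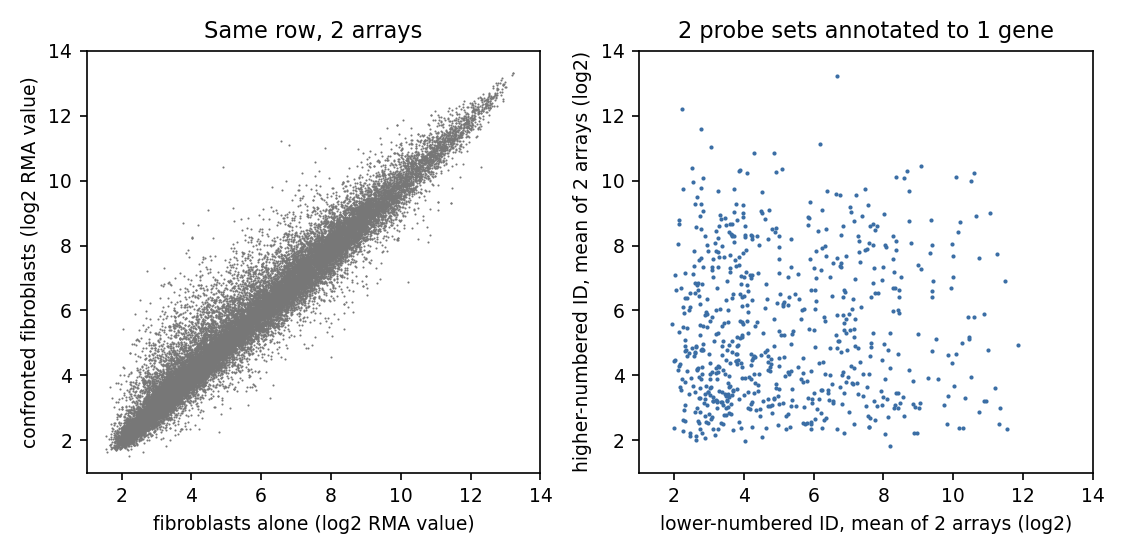
Left, value of each of the 33297 rows on the array of fibroblasts alone (x) and of confronted fibroblasts (y), in log2 RMA units, with a Pearson correlation of 0.975. Right, mean of the 2 arrays for the probe sets of each of 689 genes with 2 probe sets, with a Pearson correlation of 0.04.

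Counts over rows can be made without gene names. Of the 29094 rows from the lowest annotated ID upwards, 884 (3.04%) were at least 2-fold higher on the confronted array and 453 (1.56%) at least 2-fold lower. The median difference of these rows was -0.03 and its standard deviation over rows 0.48. The planned counts were made over the 8988 genes kept by the filter on level, a set of rows that was chosen through the gene names and so rests on the pairing. In that set 418 were at least 2-fold higher, 207 at least 2-fold lower and 8363 within 2-fold. The excess of higher genes depends on the threshold, since at 1.5-fold it turned, with 905 higher and 950 lower, while at 3-fold 151 were higher and 64 lower. Their differences had a standard deviation of 0.58 and a robust one of 0.40, and 98% of them lay between -1.39 and 1.89. The standard deviation was 0.63 over the 1798 genes of lowest level and 0.51 over the 1798 of highest level. The largest difference in this set, 5.52, was that of the row with ID 7938072, with 4.91 on the array of fibroblasts alone and 10.43 on the confronted array. The fixed rule leaves this row out because its ID is annotated to an olfactory receptor. The largest positive differences picked by the rule were those of the rows with IDs 7925500, with 3.75 and 8.69, and 8043639, with 6.57 and 11.21. The largest negative differences were those of the rows with IDs 8037355, with 7.99 and 4.58, and 8044191, with 10.21 and 6.89. These IDs only mark rows, since the pairing of values with IDs was not borne out. The filter and the exclusions of the rule rest on the same pairing. A block of 4203 rows below the lowest annotated ID entered none of these counts. Its median difference was 0.33. With 1 array per group, all of these values hold for these 2 arrays alone.

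**Figure D3:**
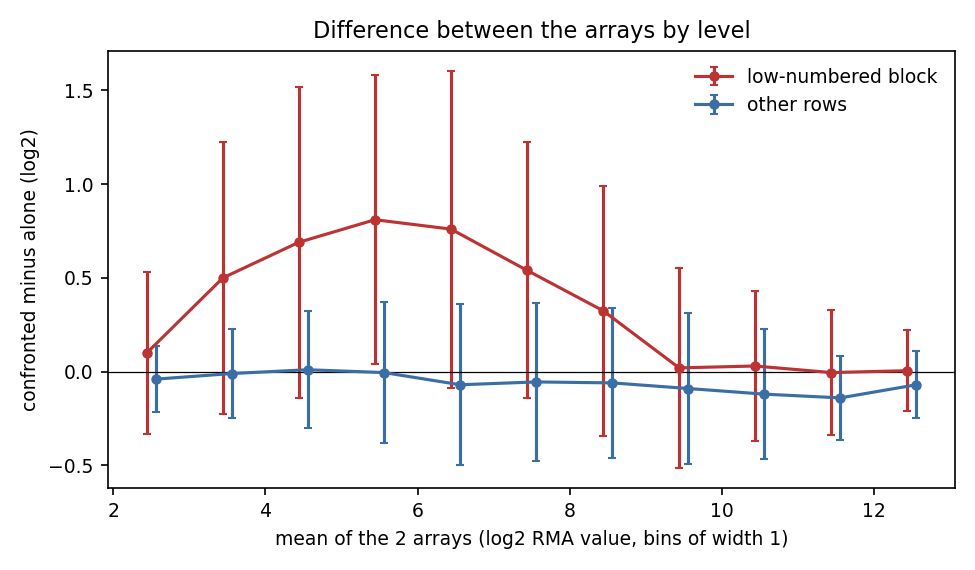
Median difference between the arrays (confronted minus alone, log2) by the mean level of a row, in bins of width 1, for the 4203 rows below the lowest annotated ID (red) and the 29094 other rows (blue). Bars are the robust standard deviation over rows; the red points reach 0.81 at levels from 5 to 6 and the blue points stay between -0.14 and 0.01.

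The fixed gene lists, read through the same pairing, gave medians close to those of random lists. The medians of the 34 lists ran from -0.13 to 0.14, and 55 of the 605 list entries measured were at least 1.5-fold higher and 39 at least 1.5-fold lower. That is 15.5% of the entries, against 13.9% of all genes. 1 list stood apart, where 1.7 would by chance. It was the list of NF-kappaB feedback genes and targets, with a median of 0.14 over 18 genes, a percentile of 98.6, and 3 genes at least 1.5-fold higher, 1 lower and 14 within 1.5-fold. The row assigned to TNFAIP2 had a difference of 2.17, that of TNIP3 0.96, that of REL 0.69 and that of NFKB1 -0.65. The row of NFKBIA, the inhibitor that the pathway itself induces, had a difference of -0.03 at a level of 3.18. The value of this list depends on the setting. With random lists not matched on level its percentile was 97.3 and neither it nor any other list stood apart. With members at or above the median level it had 0.48 (percentile 99.3) and 2 lists stood apart, and as a mean it had 0.28 (percentile 99.5) and 3 did. Chemokines had a median of 0.03, interferon-stimulated genes 0.02, cell cycle and mitosis genes -0.05, p53 targets 0.04, collagens 0.11 and myofibroblast genes -0.11, and none of these stood apart. Because the pairing was not borne out, none of these values can be attributed to the named pathway.

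3 genes for secreted proteins had been fixed for naming whatever their values. The row assigned to GDF15, a stress-induced member of the TGF-beta superfamily, had 4.70 in fibroblasts alone and 4.69 in confronted fibroblasts. The row of DKK1, an inhibitor of WNT signalling, had 2.36 and 2.20, and that of EMILIN1, an elastic fibre glycoprotein, had 3.23 and 3.42. Each difference was smaller than the robust standard deviation of differences over the rows from the lowest annotated ID upwards within the same log2 unit of level, which was 0.31 for GDF15, 0.18 for DKK1 and 0.24 for EMILIN1. By mean level these rows lay at percentiles 45.6, 2.9 and 22.3 of all genes. Since the pairing was not borne out, the values do not show whether the 3 genes themselves changed.

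Carry-over of tumor cells into the confronted sample could not be assessed. The 29 epithelial and PC3 carcinoma markers had a median difference of -0.02 at percentile 64.0, with 4 at least 1.5-fold higher and 1 at least 1.5-fold lower. Their mean difference was 0.19, at percentile 97.9 among means of random lists, so that by the mean the list stood apart and by the median it did not. The rows assigned to S100P and LCN2 differed by 3.35 and 2.77, that of the basal keratin KRT5 by 1.32 and that of LAMB3, a laminin chain, by -1.70. None of these is evidence on tumor cells while the pairing stands as it does. Those of EPCAM, KRT8 and KRT18 differed by 0.16, -0.30 and -0.23. Endothelial and leukocyte markers, which neither culture should express, had median differences of -0.01 and 0.04, with 3 of 10 and 0 of 10 rows past 1.5-fold.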

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

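All tests in this part were chosen after the results had been seen. In a block of 4203 rows below the lowest annotated ID (7892501 to 7896738), which entered no count of genes and no gene list above, 21.5% of rows were at least 2-fold higher on the array of confronted fibroblasts and 1.36% at least 2-fold lower, against 3.04% and 1.56% of the other 29094 rows, which is why it was singled out. Its mean was 5.83 on the array of fibroblasts alone and 6.28 on the confronted array, and its median difference was 0.33, against -0.03 both for the other rows and for the 7858 unannotated rows among them. A trend of the difference with level is argued against, because the block exceeded other rows of the same level by a median of 0.37, whereas random rows gave -0.01 to 0.01; medians were 0.81 against -0.01 at levels from 5 to 6 and 0.01 against -0.07 from 12 to 13. On arrays of this type low IDs hold the manufacturer's control probe sets, some for introns and for background, so a candidate explanation is more signal from unspliced RNA, genomic DNA or background on the confronted array. It stays open, because the annotation gives a class for 0 of these rows, and an effect of the exposure itself is not excluded with 1 array per group.

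The levels of named genes are the second pattern, and rows out of order against their IDs above the low-numbered block may account for it, since 2 probe sets of 1 gene had a correlation of 0.0404 in mean level while the arrays agreed row by row. Disorder over the whole table is argued against, since the block and the other rows would then have the same median difference. These were 0.36 apart, and 95% of 1000 shuffles gave gaps from -0.01 to 0.01. The shuffles moved finished rows, so they cannot decide whether probes were read from wrong positions over all of the array. A common shift or reversal of gene-specific levels is argued against. Ribosomal protein rows exceeded olfactory receptor rows by at most 1.0002 log2 units over 33297 offsets in each direction. In the simulation, shuffled rows gave at most 1.182 and a known shift gave 7.94. The simulated ribosomal rows had been set high and the olfactory ones low, so 7.94 is not the excess that real levels would give. A shift of nonspecific signal would not show in this comparison. True levels of these cells under correct IDs are argued against because probe sets with the same accessions would be alike, and their intraclass correlation of level was 0.0021. Nonspecific signal under correct IDs depends on each probe, so it could also give such a value if those probe sets carry different probes. Whether they do is not given in the sources used here. Nonspecific signal therefore stays open beside rows out of order, as do disorder within the block and a misreading of part or all of the array. No biological explanation was tested further.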

How the results depend on the processing

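No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. The count of genes at least 2-fold higher was between 375 and 583 and that of genes at least 2-fold lower between 174 and 268 over the 8 planned changes of filter, probe set rule and normalization, all within 1.5 times the values of 418 and 207. Genes with a higher value made up 66.9% of the genes past 2-fold, 72.8% after the trend with level was removed and 59.8% after a further quantile normalization. That normalization was made over all 33297 rows, so the low-numbered block took part in it. With it the median difference of all genes went from -0.03 to -0.085. How much of the lower percentage came from the block was not tested. The excess of higher genes turned at a 1.5-fold threshold, with 905 higher and 950 lower, and not at 3-fold, with 151 and 64. Chosen after seeing the data, counts over all rows outside the low-numbered block were 884 and 453, and over those at or above their median level 647 and 364; more rows were counted there. The spread of the differences was 0.48 without the filter and 0.58 without the trend. The number of lists that stood apart was 1, and became 2 with members at or above the median level, 3 with the mean of a list and 0 with random lists not matched on level. The NF-kappaB list had 0.48 with members at or above the median level and 0.28 as a mean, and with unmatched random lists its median of 0.14 no longer stood apart. Of the other lists, the WNT list stood apart at 0.39 with members at or above the median level, and the epithelial and housekeeping lists at 0.19 and 0.39 as means; the cause was not tested. These settings leave the pairing of values with IDs as it is, so none of them bears on whether a gene name is right. No file used here gives signal over background, so which low values are above it is unknown.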
